A study of Schizosaccharomyces pombe with 10 samples.

How the data were processed

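PolyA RNA sequencing measured transcripts in the fission yeast Schizosaccharomyces pombe, grown in minimal medium and collected untreated or after 15 min in 1 mM H2O2. The 10 libraries came from 5 strains, named here by the labels: WT (wild type), STY (sty1 deletion), HA (sty1 deletion with HA-tagged Atf1), 10D (sty1 deletion with the phosphomimicking Atf1) and 10M (sty1 deletion with the unphosphorylatable Atf1). Sty1 is the stress-activated MAP kinase and Atf1 a bZIP transcription factor that it phosphorylates. Each strain and treatment had 1 library, so no strain was replicated.

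The authors stated that read quality was checked with FastQC, that reads were aligned with TopHat2 2.1.1 and that they were counted per gene with HTSeq. The deposited table holds raw counts, the number of reads per gene, and its columns were joined to the samples by the column names that the sample descriptions give. The genome build, the annotation, the strand setting and any filter were not stated. Of 7017 genes in the table, 6843 matched the names of the ASM294v3 reference and 174 did not; the match supplied symbols, and coordinates were not used here. Because the strand setting was not stated, reads from overlapping or antisense transcripts cannot be told apart in a count.

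Library totals were 9613009 counts in untreated and 9526891 in treated WT, 9309966 and 9670548 in STY, 9178795 and 10745498 in HA, 17111861 and 26503471 in 10D, and 16920081 and 17780370 in 10M. A count of 0 allowed up to 3 counts, which was 0.113 to 0.327 CPM across libraries. The 10 most abundant genes took 7.29% to 11.6% of a library and noncoding genes 0.868% to 1.54%. Intervals for single genes and floors cover counting error only, and may understate it, since reads amplified by PCR are not independent molecules. Intervals for the median of a list or set cover the spread between its genes, taken as independent. Neither kind covers the spread between repeat libraries. The 10D and 10M libraries were deeper than the rest, no label names a batch, and a batch that follows strain cannot be separated from strain.

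Counts were scaled with edgeR's TMM factors, which ran from 0.919 to 1.11. Within each strain, treated and untreated libraries were compared by the log2 ratio of scaled CPM with a prior count of 2, over the 4985 genes with a mean of at least 10 CPM. A gene counted as apart when the ratio reached 2-fold and its exact binomial 95% interval excluded 1. The wild-type induced set held genes at least 4-fold higher in treated than in untreated WT; it was scored in the other strains, with a 95% order-statistic interval for each median. Correlations of responses were taken across genes, which are not independent replicates.

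Tests across all genes used edgeR quasi-likelihood fits with filterByExpr and Benjamini-Hochberg adjusted p below 0.05. The shared H2O2 response came from a fit of strain and treatment on 10 libraries (6097 genes, 4 residual degrees of freedom). A fit of 6 cell means placed STY, HA and 10M in 1 pool per treatment, beside WT and 10D (6176 genes, 4 residual degrees of freedom). There the spread between the 3 pooled strains was the error, and each lone WT or 10D library was assumed to vary as they did. A fit of strain and treatment on the 8 libraries labelled as sty1 deletion (6133 genes, 3 residual degrees of freedom) compared HA with STY, and 10M and 10D with HA. Errors, written as SE, are the absolute log2 change divided by the square root of the test's F statistic, not a separate estimate. They rest on differences between strains rather than between repeats of a strain. The contrast of the 10D response with the WT response, and 3 measures on the wild-type induced set (treated 10D, treated 10M, and untreated 10D over untreated 10M), were added after the data had been seen.

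Apart from those additions and from leaving out single libraries for HA against STY, 10M against HA and 10D against HA, the comparisons, alternatives, rule for named genes and 18 gene lists were fixed before the data were examined. The lists were Sty1-Atf1 stress genes, Pap1-linked oxidative stress genes, antioxidant and thiol redox enzymes, heat shock proteins and chaperones, trehalose and glycerol metabolism, glycolysis, ribosomal proteins, ribosome biogenesis, Sty1 pathway components, mating and meiosis, iron uptake, amino acid biosynthesis, phosphate acquisition, G1-S transcripts, histones, cell separation and septum genes, the retrotransposon Tf2, and housekeeping controls. They held 474 matched names, several in more than 1 list, and 1 name was not matched. Most trehalose and glycerol genes are also in the Sty1-Atf1 stress list, so the results of those lists are not separate. Lists were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 18 lists within a contrast. Within a strain, a list's median was ranked among 10000 random lists drawn from 10 expression bins; the genes they were drawn from, those with a mean of at least 1 CPM (5967 genes), were chosen when the calculation was written. Named genes were sty1, atf1 and markers; the 8 highest and 8 lowest called changes of each fitted comparison with at least 10 CPM; the 5 highest and 5 lowest ratios of each strain; the 2 highest and 2 lowest members of each list in the WT response; and 19 fixed genes (ctt1, gpx1, gpd1, hsp9, srx1, pyp2, ntp1, tps1, trr1, obr1, hsp16, hsp104, cta3, fbp1, gld1, tpx1, pap1, ste11 and act1). Fewer were named where the text was long enough without them.

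Alternatives were DESeq2 size factors, total counts alone, DESeq2's Wald test, no low-count filter, noncoding genes left out, strain as a block, other prior counts (0.5 and 5), other CPM minimums (1, 50 and 100), other folds for the wild-type induced set (2 and 8), libraries thinned to 9178795 counts, and each strain or library left out. The fits were tested on simulated data. The shared-response fit recovered 88% of genes changed 2-fold and 98% of those changed 4-fold, with 9 false calls of 200. These rates describe simulated data and may be better than those in the real libraries. Real differences in response between strains add to the error of that fit. Its common dispersion was 0.083, above the 0.054 of the fit of cell means. With the real libraries its calls fell to 0 when WT, HA or 10M was left out. The contrast of treated WT with the pool recovered 34% and 88%, with 10 false calls of 167, and the contrast of responses for 10D recovered 10% and 68%, with 10 of 139. Whether treated and untreated libraries of a strain belonged together was checked by correlating their deviations from the pool. Each treated library of the pool correlated most with its own strain (0.49 in STY, 0.43 in HA and 0.72 in 10M). WT and 10D, which lie outside the pool, were not checked in this way. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.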

Results

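The series asked how gene expression, at rest and after H2O2, depends on forms of Atf1 that mimic or prevent phosphorylation when the kinase Sty1 is missing. The 10 count libraries were compared, 1 untreated and 1 treated with 1 mM H2O2 for 15 min for each of WT, STY, HA, 10D and 10M. Library totals ran from 9178795 to 26503471 counts, and no strain was replicated.

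The sty1 transcript (SPAC24B11.06c) and the label of each library were compared first. Its scaled level was 266.7 and 305.2 CPM in untreated and treated WT and 8.92 and 9.11 CPM in STY. The libraries labelled HA, 10D and 10M, which the labels give as sty1 deletions, held between 101 CPM (untreated 10M) and 129.9 CPM (treated 10D). The labels of these 3 strains are therefore not matched by their sty1 counts, and every statement on them names the library by its label. The atf1 transcript (SPBC29B5.01) was at 143 and 643 CPM in WT, 69.3 and 30.4 CPM in STY, 556 CPM in untreated HA with a treated level higher by 0.25 on the log2 scale, 524 and 744 CPM in 10D, and 358 and 398 CPM in 10M. Among marker genes, leu1 was at 539.5 and 680.1 CPM in WT and at 2767 to 5573 CPM in HA, 10D and 10M, while ura4 stayed between 89.4 and 255 CPM in all libraries.

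Treated against untreated wild type asked which transcripts were higher or lower after H2O2. In WT, 793 genes were at least 2-fold apart, 470 higher and 323 lower in the treated library. The catalase gene ctt1 (SPCC757.07c) was higher by 7.0 on the log2 scale (interval 6.92 to 7.077), the sulfiredoxin gene srx1 (SPBC106.02c) by 6.84 (6.70 to 7.0) and shu1, which takes up heme, by 7.04 (6.67 to 7.53). The peroxiredoxin gene tpx1 was higher by 3.37, the thioredoxin reductase gene trr1 by 4.46, and the phosphatase gene pyp2, whose product acts on Sty1, by 4.27. Among the 5 lowest ratios were those of dgc1 (−5.84), isp5 (−5.61) and the mating pheromone gene mfm1 (−5.05). The Sty1-Atf1 stress list had a median of 2.20, with 20 of 29 members at least 2-fold higher and 0 lower, above every one of 10000 random lists. Medians were 3.75 for Pap1-linked genes, 0.98 for antioxidant enzymes, −0.91 for heat shock proteins and −1.71 for glycolysis.

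The same ratio in the other strains asked how much of that response each one showed. STY had 393 genes at least 2-fold apart (57 higher, 336 lower), HA 579 (202 and 377), 10D 729 (368 and 361) and 10M 313 (148 and 165). In STY, the stress list had a median of −0.01, ctt1 was higher by 1.24 and srx1 by 0.56. In 10D, srx1 was higher by 6.58, trr1 by 4.82 and ctt1 by 3.78, but hsp9, a small stress protein, had a ratio of −2.12, gpd1, a glycerol-3-phosphate dehydrogenase, −1.40 and tps1, a trehalose-6-phosphate synthase, −2.26. The stress list in 10D had a median of −1.17, with 2 of 29 members at least 2-fold higher and 16 lower, while Pap1-linked genes had 2.79. The chaperone genes hsp16 and hsp104 had ratios of 1.75 and 1.38 in STY, 3.83 and 2.27 in HA, and 2.76 and 0.86 in 10M, against −0.79 and −0.96 in WT and −4.01 and −3.81 in 10D. Under total counts the median of all genes moved from −0.07 to −0.23 in WT, from −0.03 to −0.19 in STY and from −0.09 to −0.24 in HA, and of the genes apart 44.1% rather than 59.3% were higher in WT, 8.78% rather than 14.5% in STY and 23.5% rather than 34.9% in HA. With a minimum of 50 CPM the counts were 475, 205, 259, 446 and 126 for WT, STY, HA, 10D and 10M.

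**Figure D1:**
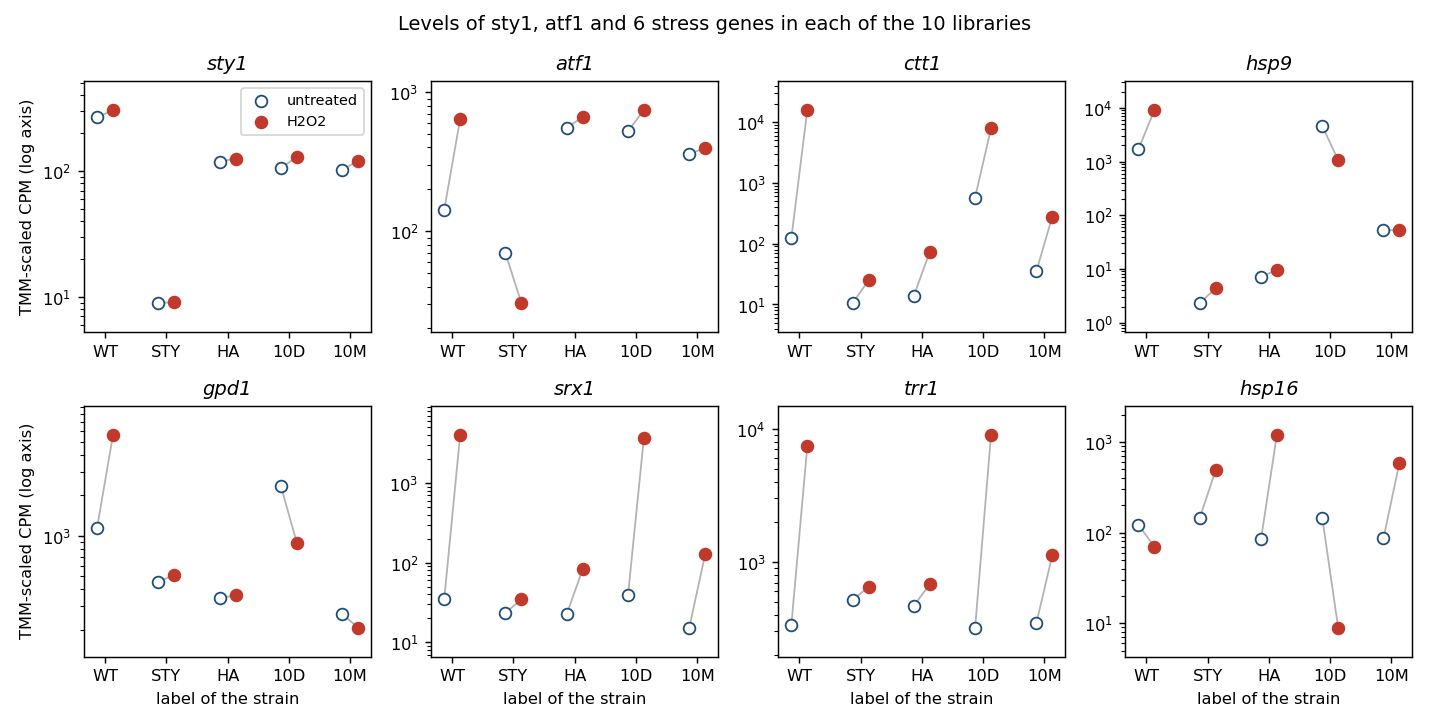
Scaled level (TMM-scaled CPM, log axis) of sty1, atf1 and 6 stress genes in each untreated and H2O2 treated library of the 5 strains, with untreated libraries as open and treated ones as filled points. The ctt1 transcript went from 124 to 15870 CPM in WT and ended at 7903 CPM in treated 10D, and hsp9 from 4640 to 1069 CPM in 10D.

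A set of 164 genes at least 4-fold higher in treated WT gave a measure of the wild-type response that used none of the WT libraries for scoring. Their median log2 response was 0.16 in STY (interval 0.07 to 0.27), 0.45 in HA (0.33 to 0.69), 0.41 in 10M (0.21 to 0.67) and 1.26 in 10D (0.92 to 1.99). The STY median was far smaller with the set taken at 2-fold or under total counts, and the 10D median was larger at 8-fold. At least 2-fold higher were 7.93% of the set in STY, 28.7% in HA, 28.0% in 10M and 56.7% in 10D. Before treatment, the set was already higher in 10D than in STY and HA, by a median of 1.26 (0.76 to 1.67), and in 10M by 0.37 (0.18 to 0.61). Both untreated medians were smaller with the set taken at 2-fold. After treatment the medians over STY and HA were 2.48 in 10D (2.32 to 2.87) and 0.54 in 10M (0.37 to 0.70). Across genes, which are not independent replicates, the WT response had a Pearson correlation of 0.68 with 10D (Spearman 0.67), 0.29 with 10M (0.21), 0.26 with HA (0.18) and 0.10 with STY (−0.03). HA and 10M correlated at 0.87 (0.87), and STY with 10D at 0.02 (−0.06).

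**Figure D2:**
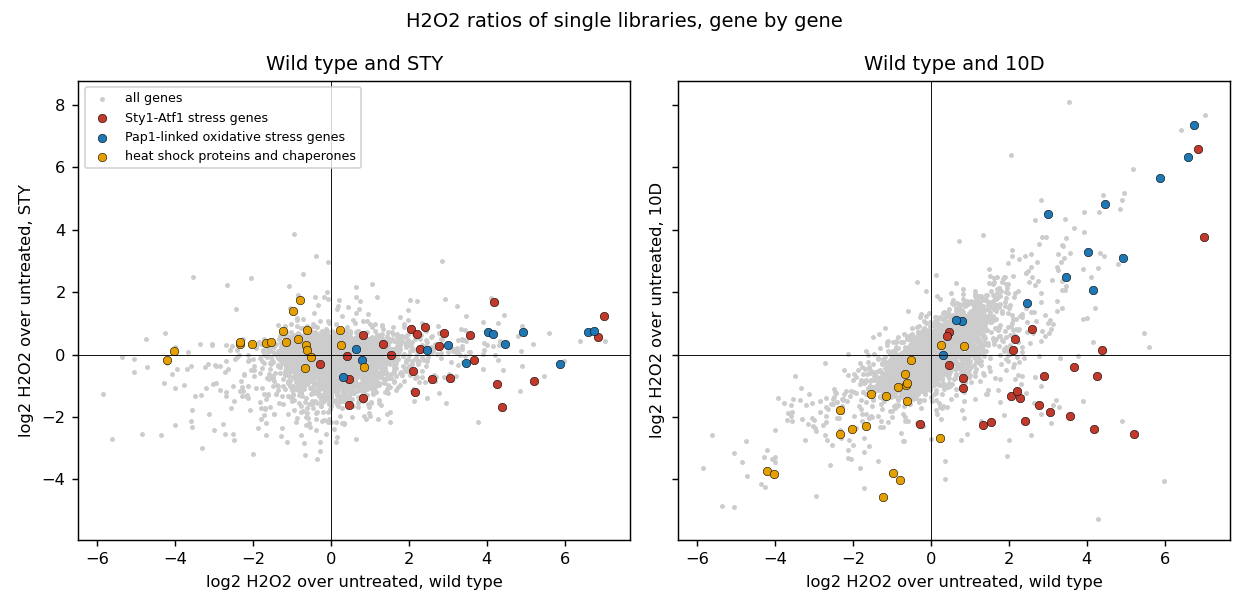
Log2 ratio of treated over untreated counts in WT (horizontal) against STY and against 10D (vertical), 1 point per gene with a mean of at least 10 CPM, and 3 gene lists in colour. The correlation across genes was 0.10 with STY and 0.68 with 10D, and 16 of 29 stress genes were at least 2-fold lower in 10D.

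The response shared by the 5 strains was tested with strain and treatment in the fit. The kinase gene oca2 rose by 3.01 (SE 0.391, adjusted p = 0.0314), pof15 by 2.37 (SE 0.37) and the ammonium transporter gene amt3 by 2.23 (SE 0.453). The fit tests a mean over strains, and a called gene need not move equally in each. The log2 ratio of amt3 was 0.46 in STY, against 1.94 in 10M, 1.98 in HA, 3.08 in 10D and 3.40 in WT. The meiosis gene mei2 fell by 3.21 (SE 0.453, adjusted p = 0.0314), slp1, an activator of the anaphase-promoting complex, by 2.40 (SE 0.303), eng1, a glucanase that separates daughter cells, by 2.35 (SE 0.326), and ste11, the transcription factor for mating, by 2.091 (SE 0.228). Of 15 cell separation genes, 8 fell and 0 rose (12 fell adjusted over the list alone), with a median of −1.06 and a camera adjusted p = 2.31e-07, against adjusted p = 0.58 with an estimated correlation. G1-S transcripts had 3 of 12 members fall (9 adjusted over the list alone), and of 20 mating genes 6 fell and 0 rose (1 rose and 11 fell adjusted over the list alone). Among 40 amino acid genes 0 were called by edgeR over all genes and 8 rose and 1 fell adjusted over the list alone. The 9 housekeeping controls had a median of −0.01 and 0 calls (camera adjusted p = 0.729). In all, 299 genes passed, 126 higher and 173 lower. Of the called genes 42.1% were higher, against 49.8% under DESeq2 size factors, so the excess of lower calls depended on the scaling. Without WT, HA or 10M 0 genes passed, without STY 3 and without 10D 6, while 1821 genes had an unadjusted p under 0.05 and DESeq2 called 1140. Without noncoding genes 142 passed.

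The response of the 3 pooled strains, STY, HA and 10M, was tested on its own, with the sty1 counts of HA and 10M against their labels. The chaperone genes hsp16 and hsp104 rose, by 2.85 (SE 0.404, adjusted p = 0.0116) and 1.47 (SE 0.341, adjusted p = 0.0321). Of 20 heat shock genes 6 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.62 (camera adjusted p = 5.05e-05, and adjusted p = 0.563 with an estimated correlation). The sulfiredoxin gene srx1 rose by 2.02 (SE 0.452, adjusted p = 0.0298), while 1 of 29 Sty1-Atf1 stress genes rose and 3 fell, with a median of 0.08 (camera adjusted p = 0.933, direction down). The oxygenase gene isp7 fell by 3.66 (SE 0.367, adjusted p = 0.00723), and 8 of 15 cell separation genes and 7 of 12 G1-S transcripts fell (10 and 9 adjusted over the list alone). In all, 957 genes passed, 320 higher and 637 lower. Of the called genes 33.4% were higher, against 41% under DESeq2 size factors. With strain as a block 1937 passed, without STY 67 higher and 72 lower, and without HA 0.

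Wild type against the pool asked which transcripts differed between WT and strains with the labelled deletion. The pool held sty1 counts in HA and 10M. Its strains also differed from WT in their atf1 level, given above, or in the form of Atf1. A difference in this contrast therefore cannot be assigned to the deletion alone. In treated WT, ctt1 was higher by 6.97 (SE 1.15, adjusted p = 0.00506), hsp9 by 8.64 (SE 1.71, adjusted p = 0.00909), srx1 by 5.63 (SE 0.57), pyp2 by 4.80 (SE 0.521), the glutathione peroxidase gene gpx1 by 4.55 (SE 0.733) and gpd1 by 3.97 (SE 0.441). Of 29 Sty1-Atf1 stress genes 21 were higher and 0 lower (22 and 0 adjusted over the list alone; median 3.50, camera adjusted p = 1.56e-08, and adjusted p = 0.432 with an estimated correlation). Pap1-linked genes had 10 of 14 higher and antioxidant enzymes 11 of 20, and trehalose and glycerol genes had 6 of 10 higher, with the same numbers adjusted over the list alone. Heat shock genes were lower in 18 of 20 cases and higher in 1, hsf1, the heat shock transcription factor, and glycolysis genes in 13 of 14, again the same adjusted over the list alone, with hsp16 at −3.44 (SE 0.669) and medians of −2.46 and −2.48. Of 131 ribosomal protein genes 56 were lower (77 adjusted over the list alone). With an estimated correlation the adjusted p was 0.254 for Pap1-linked, antioxidant and glycolysis genes, 0.357 for heat shock genes and 0.443 for trehalose and ribosomal genes. In all, 2343 genes passed, 1329 higher and 1014 lower in WT, and 716 passed without HA. In untreated libraries 4 genes passed, nrg1 (6.61, SE 0.511), SPCC569.03 (5.003, SE 0.459) and tam13 (2.29, SE 0.234) higher and SPAC750.01 lower (−6.74, SE 0.677). There the stress list had a median of 1.01 with 0 of 29 members called by edgeR, 6 higher adjusted over the list alone (camera adjusted p = 6.51e-08, and adjusted p = 0.613 with an estimated correlation). In that untreated contrast 431 genes had an unadjusted p under 0.05, DESeq2 called 66, and 2 passed without STY, 0 without HA and 42 without 10M.

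The difference between the WT response and that of the pool was tested as an interaction. The response in WT was larger for the cation transporter gene cta3 by 6.09 (SE 1.09, adjusted p = 0.03), pyp2 by 4.84 (SE 0.876), srx1 by 4.83 (SE 0.943), trr1 by 3.58 (SE 0.544) and tpx1 by 2.82 (SE 0.48). It was lower for the chaperone genes ssa2 (−4.27, SE 0.447, adjusted p = 0.0125), hsp90 (−4.26, SE 0.378) and hsp16 (−3.65, SE 0.798). Of the Pap1-linked genes 6 of 14 were higher, of stress genes 8 of 29 and of antioxidant enzymes 6 of 20 (10, 11 and 7 adjusted over the list alone), with 0 lower in each, and their camera adjusted p were 1.51e-07, 4.96e-06 and 0.00133. For these lists the adjusted p was 0.133, 0.483 and 0.133 with an estimated correlation. Heat shock genes were lower in 9 of 20 cases and glycolysis genes in 8 of 14 (14 and 13 adjusted over the list alone; camera adjusted p = 1.57e-09 and 5.27e-10, and adjusted p = 0.382 and 0.133 with an estimated correlation). In all, 336 genes passed, 214 higher and 122 lower. With strain as a block 1059 passed, DESeq2 called 807, and without STY or HA 0 passed against 650 without 10M.

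The library labelled 10D against the pool asked what differed at rest in the strain with the phosphomimicking Atf1. The pooled strains differed in their atf1 level, given above and far lower in STY than in HA and 10M. This contrast therefore does not separate the amount of atf1 transcript from the form of Atf1. In untreated 10D, nrg1 was higher by 7.95 (SE 0.513, adjusted p = 0.000545), ddr48 and the stress gene lsd90 by 6.11 (SE 0.659) and 5.94 (SE 0.507), gpd1 by 2.72 (SE 0.44, adjusted p = 0.0236) and tps1 by 1.996 (SE 0.376, adjusted p = 0.0437). The galactosidase gene mel1 was at 68.3 CPM, with 0 counts in untreated STY and HA and 0.164 CPM in 10M. Of 29 stress genes 8 were higher and 0 lower (18 and 0 adjusted over the list alone; median 2.33, camera adjusted p = 4.57e-13), and of 10 trehalose and glycerol genes 3 were higher (8 adjusted over the list alone; median 2.13, camera adjusted p = 4.73e-06). Both had adjusted p = 0.499 with an estimated correlation. Pap1-linked genes had a median of −0.35 with 2 of 14 higher, the same adjusted over the list alone, and heat shock genes had a median of 0.01 with 0 of 20 called by edgeR over all genes. The flocculin genes pfl8 and pfl3 were lower by −3.19 (SE 0.469) and −2.69 (SE 0.497). In all, 165 genes passed, 143 higher and 22 lower, and 901 had an unadjusted p under 0.05. DESeq2 called 402, and 48 passed without STY, 25 without HA and 430 without 10M.

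After H2O2, the library labelled 10D differed from the pool at more genes. There shu1 was higher by 8.51 (SE 0.361, adjusted p = 0.000108), ctt1 by 5.95 (SE 1.12, adjusted p = 0.00959), srx1 by 5.50 (SE 0.568), trr1 by 3.46 (SE 0.331), gpx1 by 2.62 (SE 0.726) and tpx1 by 2.04 (SE 0.301), while hsp16 (−6.42, SE 0.799), ssa1 (−5.79, SE 0.912) and hsp104 (−4.59, SE 0.638) were lower. Of 29 stress genes 13 were higher and 0 lower, the same adjusted over the list alone (median 1.41, camera adjusted p = 0.000328, and adjusted p = 0.65 with an estimated correlation), and 10 of 14 Pap1-linked genes were higher (11 adjusted over the list alone; median 2.51). Heat shock genes were lower in 16 of 20 cases (18 lower and 1 higher adjusted over the list alone) and glycolysis genes in 13 of 14, both ways of adjusting. With an estimated correlation the adjusted p was 0.245 for Pap1-linked and glycolysis genes and 0.33 for heat shock genes. In all, 1914 genes passed, 1150 higher and 764 lower; 1264 passed without STY and 420 without HA. As a difference of responses, 301 genes passed, 182 higher and the rest lower, among them srx1 (4.57, SE 0.933, adjusted p = 0.0439), trr1 (3.93, SE 0.55), tpx1 (2.97, SE 0.481), hsp104 (−5.29, SE 0.744), hsp16 (−6.89, SE 0.891) and tps1 (−2.83, SE 0.597, adjusted p = 0.0473). In that test 1 stress gene was higher and 1 lower of 29, both ways of adjusting (median −1.30, camera adjusted p = 0.137), and 13 of 20 heat shock genes were lower (16 adjusted over the list alone; camera adjusted p = 2.4e-12, and adjusted p = 0.322 with an estimated correlation). With strain as a block 853 passed, DESeq2 called 744, and 3 passed without STY, 0 without HA and 485 without 10M.

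The library labelled 10D was also set against wild type. In untreated libraries opt3 was higher in 10D by 3.08 (SE 0.256, adjusted p = 0.0104) and hsp3101 by 4.09 (SE 0.357), and SPNCRNA.798 was lower (−3.32, SE 0.318). The stress list had a median of 1.65 with 0 of 29 called by edgeR over all genes, 3 higher adjusted over the list alone (camera adjusted p = 0.000145, and adjusted p = 0.749 with an estimated correlation). In treated libraries the 4 genes that passed were higher in 10D, SPAC750.01 (6.104, SE 0.573), opt3 (3.24, SE 0.253), adh8 (2.11, SE 0.22) and cbl1 (1.77, SE 0.19), and the stress list had a median of −1.89 with 0 called and 13 lower adjusted over the list alone (camera adjusted p = 1.78e-07, and adjusted p = 0.649 with an estimated correlation). The untreated contrast had 13 calls, 11 higher and 2 lower, with 1 without STY, 0 without HA and 49 without 10M, 7 without noncoding genes, and 114 by DESeq2. The treated contrast had 4 calls, with 1 without STY, 0 without HA and 17 without 10M, 153 by DESeq2, and 852 genes at an unadjusted p under 0.05. The difference of responses had 5 calls, all lower in 10D, SPAC11D3.01c (−5.20, SE 0.421, adjusted p = 0.0174), prl65 (−5.18, SE 0.458), hsp3101 (−4.61, SE 0.467), SPAC32A11.02c (−3.83, SE 0.324) and SPBC12C2.04 (−2.54, SE 0.273). In that test 0 of 29 stress genes were called by edgeR and 12 were lower adjusted over the list alone (median −3.39, camera adjusted p = 3.32e-17, and adjusted p = 0.325 with an estimated correlation). DESeq2 called 79 there, the fit with strain as a block 107, and 345 genes had an unadjusted p under 0.05; 0 passed without STY, 1 without HA and 30 without 10M.

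The last comparisons set the Atf1 forms against one another over both treatments. This fit gives all strains the same response to H2O2, while the 10D response differed from that of the pool, as described above. Values of 10D against HA therefore average over unlike responses. The unlike 10D response also adds to the error of HA against STY and of 10M against HA. A lack of calls in those contrasts therefore does not show that the strains were alike. Where 1 library of a strain is left out, the strain is fitted by its other library alone. In 10D against HA, hsp9 was higher by 8.30 (SE 0.909, adjusted p = 0.00938), ctt1 by 6.15 (SE 0.681), cta3 by 4.71 (SE 0.626), ste11 by 3.99 (SE 0.407), gpx1 by 3.18 (SE 0.362) and the gluconeogenesis gene fbp1 by 2.52 (SE 0.464, adjusted p = 0.0335), and pfl3 was lower (−2.94, SE 0.19). Of 28 stress genes 11 were higher and 0 lower (22 and 0 adjusted over the list alone; median 2.27, camera adjusted p = 6.74e-11, and adjusted p = 0.197 with an estimated correlation). In all, 426 genes passed, 296 higher and 130 lower. Without noncoding genes 260 passed, with all 10 libraries 187, and DESeq2 called 986; 30 passed without untreated HA, 0 without treated HA and 2552 without untreated 10D. In 10M against HA, 0 genes were called by edgeR, 474 had an unadjusted p under 0.05 and DESeq2 called 116, 84 higher and 32 lower. The stress list there had a median of 0.78 with 0 of 28 called and 6 higher adjusted over the list alone (camera adjusted p = 1.43e-06, and adjusted p = 0.336 with an estimated correlation). In HA against STY, sty1 itself was the 1 gene called, at 3.76 (SE 0.174, adjusted p = 0.00485); DESeq2 called 21, 159 genes had an unadjusted p under 0.05, and leaving out any of the 4 libraries ended the call.

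**Figure D3:**
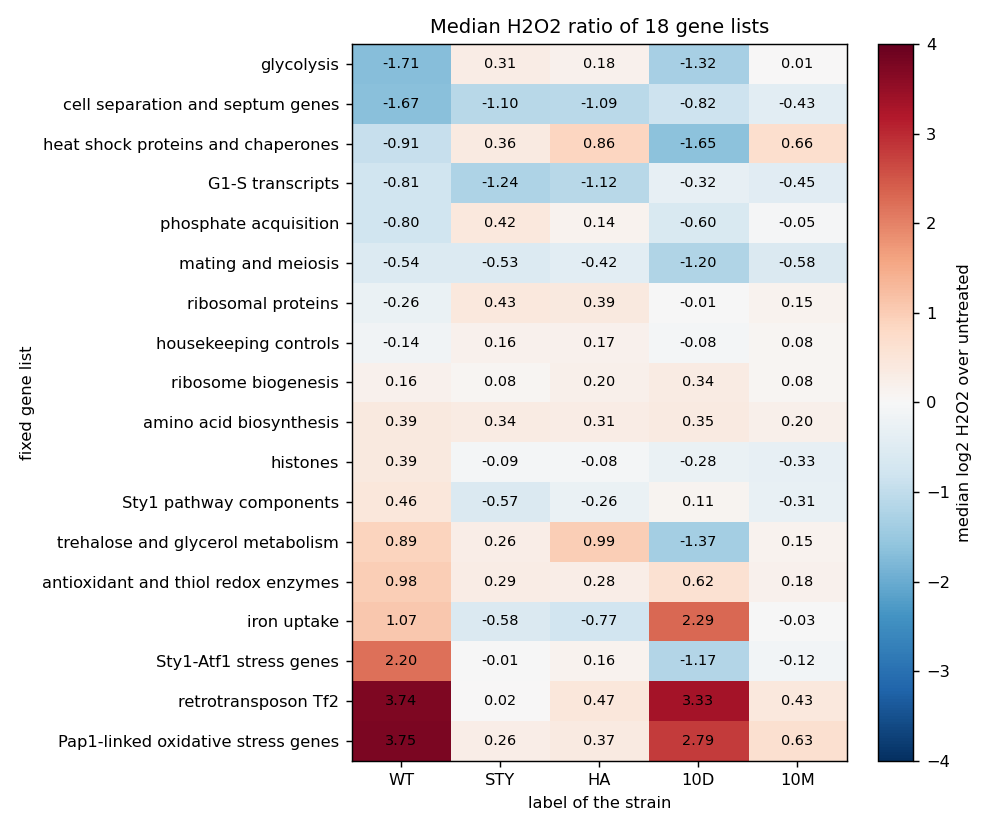
Median log2 ratio of treated over untreated counts for each of the 18 gene lists (vertical axis) in each of the 5 strains (horizontal axis), 1 library per strain and treatment, with the median printed and coloured in each cell. Sty1-Atf1 stress genes had a median of 2.20 in WT and −1.17 in 10D, and heat shock genes −0.91 in WT and 0.86 in HA; glycolysis in 10M and ribosome biogenesis in WT changed sign under total counts, which moved the median of all genes from −0.07 to −0.12 in 10M and from −0.07 to −0.23 in WT.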

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

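The tests of explanations, the splits of the samples and the contrast of the 10D response with the WT response were chosen only after the results were seen; the tests of the WT and 10D responses against the pooled strains were planned.

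The difference between the WT response and that of STY, HA and 10M passed an interaction test at 336 genes, with 1 WT library per treatment and the error taken from the 3 pooled strains. Without STY or HA 0 genes passed and without 10M 650, the fit with strain as a block gave 1059 and DESeq2 807, and 1628 genes had an unadjusted p under 0.05 in edgeR. It was positive for cta3 (6.09), pyp2 (4.84), srx1 (4.83), trr1 (3.58) and tpx1 (2.82) and negative for hsp16 (−3.65). The difference for the library labelled 10D passed at 301 genes, positive for srx1 (4.57), trr1 (3.93) and tpx1 (2.97) and negative for hsp16 (−6.89), hsp104 (−5.29) and tps1 (−2.83). It too had 1 library per treatment, and 3 genes passed without STY, 0 without HA and 485 without 10M, against 853 with strain as a block and 744 by DESeq2; 1544 had an unadjusted p under 0.05. Between 10D and WT, each with 1 library per treatment, 5 genes passed, against 107 with strain as a block, 79 by DESeq2 and 345 at an unadjusted p under 0.05, and 0 passed without STY, 1 without HA and 30 without 10M.

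The libraries labelled HA, 10D and 10M held sty1 counts above those of STY, at 39.2% of the way from the treated STY to the treated WT level in HA, 37.8% in 10M and 40.8% in 10D. Wild-type cells mixed into a library would bring all their abundant transcripts at that share. The tables argue against this in HA and 10M. The measure was taken over 109 genes with at least 100 CPM in treated WT and at least 8-fold lower in treated STY. Their median was 6.86% of the wild-type level in HA and 10.9% in 10M, under bounds of 19.6% and 18.9%. In 10D the median was 50.9%, above its bound of 20.4%, so the same rule gives no argument against mixing there. By a different rule, chosen after the data were seen, 19 of the 109 genes in 10D had intervals below 20.4%. That argues against mixing in 10D for those genes only. A sty1 sequence kept in or carried by these strains cannot be told apart from other sources, since a count per gene shows no position (39.2% in HA). No biological explanation was tested.

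Of the 29 Sty1-Atf1 stress genes, 20 were at least 2-fold higher after H2O2 in WT (list median 2.20), and 16 were lower and 2 higher in the library labelled 10D (list median −1.17). Scaling moves all genes of a library alike, and it is argued against as the cause, since the list's median in 10D less that of all genes was −1.14 (−1.92 to −0.285). Swapped 10D libraries are argued against too, since the Pap1-linked list, with a median of 3.75 in WT, had 2.79 in 10D (1.09 to 5.65), with 12 of 14 members at least 2-fold higher and 0 lower. The list also stood high in the untreated 10D library, with a median log2 ratio of 1.66 over untreated WT. There 19 of 29 members were at least 2-fold higher and 0 lower. The fall and the high untreated level share that library, so an effect of the untreated 10D library alone stays open. The strain's Atf1 form may account for the lower list, as a hypothesis that 1 library per treatment leaves untested.

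In untreated 10D against the pool, 8 of 29 stress genes were higher and 21 not called, with a median of 2.33 and adjusted p = 0.499 with an estimated correlation. If a depth or batch effect shared with the similarly deep 10M libraries were the whole cause, untreated 10D and 10M would be alike. The median log2 ratio of untreated 10D over untreated 10M was 1.84 (1.19 to 2.84) for the 29 stress genes. For the wild-type induced set this log2 ratio was 0.83 (0.48 to 1.16), so 10D stood higher. These values argue against such an effect as the whole cause. They cannot exclude a shared part, since untreated 10M also stood above STY and HA on that set, by a median log2 ratio of 0.37 (0.18 to 0.61). An effect of the untreated 10D library alone stays open, and the strain's Atf1 form may account for the levels as an untested hypothesis.

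Other splits of the samples were compared with the real one for the fits of treatment. For the response shared by the 5 strains, 1 of 100 splits, the real one with 299 genes, gave as many calls, and the highest other split, which parted 3 pairs, gave 125 genes. Since strain is in the fit, the splits to compare are the 16 that part all 5 pairs, where the highest other gave 2 genes, and 16 are too few for a share under 0.05. For the 3 pooled strains the real split gave 957 genes and the highest of the others 0, but 10 splits are too few for a share under 0.05, with 1 as large.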

How the results depend on the processing

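Leaving out libraries for HA against STY, 10M against HA and 10D against HA, the contrast of the 10D response with the WT response and the 3 added measures of the wild-type induced set were chosen after seeing the data; the other alternatives were planned. With every library kept, named genes kept direction and side of the threshold in 828 cases and lost the call in 28, list medians stayed within their spread in 297 cases and left it in 25, and counts and values stayed in 115 cases and moved in 64. With a strain or library left out, named genes kept the call in 316 cases and lost it in 329, and counts stayed in 9 cases and moved in 38. No named gene changed direction. The 10D libraries stayed in every fit of HA against STY and of 10M against HA. Their unlike response is part of the error there, so a lack of calls does not show that strains were alike. The cause was not tested for any of the changes below, except that other CPM minimums and other set folds change which genes are counted. With a minimum of 1 CPM, which lets in genes with low counts, 897 genes were at least 2-fold apart in HA and 608 in 10M.

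With a minimum of 50 CPM the genes apart were 475 in WT, 205 in STY, 259 in HA, 446 in 10D and 126 in 10M. Under total counts the median of glycolysis in 10M was −0.038 and that of ribosome biogenesis in WT −0.0040, the 2 reversals, where the scaling moved all genes alike. DESeq2 called 1140 genes for the shared response, 66 for untreated WT against the pool, 807 for the WT difference of responses, 402 for untreated 10D against the pool, 744 for the 10D difference of responses, 114 and 153 for untreated and treated 10D against WT, 79 for the difference between 10D and WT, 21 for HA against STY, 116 for 10M against HA and 986 for 10D against HA. Without noncoding genes the shared response had 142 calls, untreated 10D against WT 7 and 10D against HA 260. With strain as a block the pooled response had 1937 calls, the WT difference 1059, the 10D difference 853 and that between 10D and WT 107. With all 10 libraries 10D against HA had 187.

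With a strain or library left out, calls ranged from 0 to 6 for the shared response, 0 to 693 for the pooled response, 0 to 42 and 716 to 2658 for untreated and treated WT against the pool, 0 to 650 for the WT difference, 25 to 430 and 420 to 2406 for untreated and treated 10D against the pool, 0 to 485 for the 10D difference, 0 to 49 and 0 to 17 for untreated and treated 10D against WT, 0 to 30 for the difference between 10D and WT, and 0 to 2552 for 10D against HA. HA against STY and 10M against HA had 0 by edgeR each time, against 21 and 116 by DESeq2 and 159 and 474 at an unadjusted p under 0.05 with every library. The 10D against HA count was 0 without treated HA and 2552 without untreated 10D.

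The wild-type induced set held 470 genes at 2-fold and 75 at 8-fold. At 2-fold, 3.83% of the set in STY, 17.9% in HA and 14.7% in 10M were at least 2-fold higher, and at 8-fold 69.3% in 10D and 38.7% in 10M. Median responses were 0.019 in STY at 2-fold and 0.0159 under total counts, 0.28 and 0.69 in HA at 2-fold and 8-fold, 2.49 in 10D and 0.75 in 10M at 8-fold. At 2-fold, untreated 10D and 10M over STY and HA had median log2 ratios of 0.43 and 0.13, treated ones 1.66 and 0.34, and untreated 10D over 10M 0.33. Treated 10D had 2.96 at 8-fold, and treated 10M 0.72 under total counts. Correlations at a minimum of 100 CPM were 0.13 for WT with STY, 0.31 for WT with HA, 0.38 for WT with 10M and 0.77 for STY with HA.

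At the preset correlation camera called 9 of 18 lists for the shared response and 6 for the pooled one. For WT against the pool it called 10 untreated, 11 treated and 11 for the difference, for 10D against the pool 5, 9 and 7, for 10D against WT 6, 7 and 11, and for HA against STY, 10M against HA and 10D against HA 4, 9 and 9. With an estimated correlation limma camera called 0 in each of the 14 contrasts, and the lowest adjusted p was 0.106, for mating genes in 10M against HA.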

Other observations

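Of 12 iron uptake genes, 6 were at least 2-fold higher after H2O2 in WT and 8 in 10D, with 0 lower in either and list medians of 1.07 and 2.29, against medians of −0.58 in STY, −0.77 in HA and −0.03 in 10M. In the 10D difference of responses 5 of 12 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 4.28e-05, and adjusted p = 0.33 with an estimated correlation). Among them were shu1 (7.24, SE 0.754), str3 (6.84, SE 0.873) and the ferric reductase gene frp1 (5.10, SE 0.638, adjusted p = 0.0141). Of 4 testable Tf2 retrotransposons, 3 were higher in the 10D difference and 3 in the WT difference (3 and 4 adjusted over the list alone; camera adjusted p = 4.89e-05 and 3.41e-05, and adjusted p = 0.238 and 0.133 with an estimated correlation); Tf2 copies are near identical, so their counts depend on how shared reads were assigned. In treated WT against the pool 8 of 10 histone genes were higher, both ways of adjusting (median 1.16, camera adjusted p = 0.000398, and adjusted p = 0.321 with an estimated correlation). Of 24 Sty1 pathway components 13 were higher there (14 adjusted over the list alone; median 1.42, camera adjusted p = 0.000105, and adjusted p = 0.443 with an estimated correlation).

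In the libraries labelled 10M against HA, mating and meiosis genes had a median log2 ratio of 1.69. By edgeR 0 of 20 were called, and 11 were higher adjusted over the list alone (camera adjusted p = 2.44e-11, and adjusted p = 0.106 with an estimated correlation). The transcript of ste11 was at 70.4 CPM in untreated 10M, 13.9 in HA and 59 in WT, and mfm1 at 127 CPM in untreated 10M and 0.532 in HA. In 10D against HA 6 of 20 mating genes were higher (12 adjusted over the list alone). Of the 4 phosphate genes in HA against STY, 0 were called by edgeR and 2 were higher adjusted over the list alone (median 1.08, camera adjusted p = 1.54e-05, and adjusted p = 0.277 with an estimated correlation), with pho1, an acid phosphatase, at 95.9 CPM in untreated STY and 492 in HA. Ribosome biogenesis genes had 2 of 77 members rise in the shared response and 0 adjusted over the list alone, with a WT median of 0.16. Under total counts that median was −0.0040, while the median of all genes moved from −0.07 to −0.23, so the list stayed above it. Of the 8 highest called changes in the pooled strains 5 were noncoding transcripts, with SPNCRNA.1673 rising by 3.996 (SE 0.632, adjusted p = 0.0131).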
